A study of Homo sapiens with 9 samples.

How the data were processed

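Single-cell transcriptomes of cerebral organoids were measured in 9 libraries, 3 each of organoids kept in DMSO, DEAB or MTK. Per the labels' protocols, organoids from the H9 line received the compounds daily from day 20 to day 60, were kept in cold preservation solution, digested with enzymes at 37 °C, passed through a 40-µm strainer and cleared of red blood cells. Per the same protocols, GEXSCOPE single-cell libraries were made, pooled and sequenced on a NovaSeq6000. The submitters' processing notes give GRCh38 as the genome build. The aligner, the counting tool, the annotation, the strand handling and the rule for calling cells are not given in the sources used here.

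The deposited files hold raw UMI counts per gene symbol and cell barcode, 1 file per library, as the authors left them, and whole numbers with unequal totals were found in every file. In all, 36198 gene symbols occurred, of which 35267 had 1 position in the GENCODE annotation for GRCh38, used for coordinates and gene length. Totals over all barcodes were 25152766, 11757075 and 43643179 UMIs in DMSO replicates 1 to 3, 12147535, 29215604 and 50659385 in DEAB, and 11097422, 24360062 and 10045899 in MTK. Depth per library is the total UMI count of the kept cells, from 9098079 to 40784226, since numbers of reads are not given in the sources used here.

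Cells with at least 300 detected genes and at most 20% mitochondrial UMIs were kept. Scrublet's automatic threshold marked at most 4 cells in any library, so doublets were removed by rank as fixed before the data were examined, taking the highest scores at a rate of 0.8% per 1000 cells, 8653 cells in all. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch key, leaving out mitochondrial and ribosomal protein genes. Clusters came from 30 principal components, 15 neighbours and Leiden at resolution 1, without integration of the libraries. They were named from cell type markers and merged into neuron-like cells, progenitor-like cells and 1 unnamed cluster. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

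The library was the unit of every test. Counts were summed per library over all kept cells and over each class with at least 30 cells per library, and fitted over all 9 libraries with the edgeR 4.0.16 quasi-likelihood functions in R 4.3.3, with TMM scaling and filterByExpr. Contrasts were MTK against DMSO, DEAB against DMSO and MTK against DEAB, 2-sided, with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. Log2 fold changes are edgeR estimates, and their SE is the size of the estimate divided by the square root of the F statistic. CPM values use the library totals after TMM scaling, and camera and the agreement of the responses use log2 CPM with a prior count of 2. The difference of a response between neuron-like and progenitor-like cells was tested with library effects in the same model. Gene lists of at least 5 tested members, written before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each contrast, and again with an estimated correlation. The counts adjusted over the list alone take the genes of a list as the only genes tested. Shares of cells and quality measures were compared by exact permutation of the libraries over the 3 groups (1680 assignments), 2-sided and adjusted over the classes, clusters or measures. The agreement of the responses was compared with 50 simulated data sets in which neither compound had an effect and the libraries were independent.

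The rule for named genes was fixed before the data were examined, as were the main settings. It took the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, at least 10 CPM in a group and no overlap of the libraries, with 5 and 5 in the unnamed cluster, and the 5 smallest p where none passed. It further took up to 4 members of each list described, members of the retinoic acid synthesis, retinoic acid receptor and leukotriene lists, and cell type markers. For the interaction, genes already named by this rule were given. A gene that led the unnamed cluster in the markers, KLKP1, was left out of the results within that cluster.

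In simulated counts of this size with known changes, edgeR found 66.23% of genes changed 2-fold and 39.13% of those changed 1.5-fold in all cells, with 9 other genes of 17420 called, and 61.76% and 66.67% of those changed 2-fold in neuron-like and progenitor-like cells. The share of neuron-like cells in a library has an exact 95% binomial interval as wide as 65.9% to 68.7% in DMSO replicate 2, the library with the fewest kept cells. Pairs of libraries were checked for duplicates, and none was found.

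Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, fits of only the 2 groups compared, the replicate number as a block, all barcodes, a stricter filter (at least 1000 genes, at most 10% mitochondrial UMIs), doublets kept, equal depth, equal cell numbers, other resolutions, clustering per library, minimums of 10 and 100 cells, prior counts of 0.5 and 10, and leaving out each library. Added after the data were seen were a batch term for the 3 libraries high in lung transcripts, only the other 6 libraries, all cells without the unnamed cluster, progenitor-like cells without cluster 4 (for their own calls and for the interaction), equal cluster shares, and clustering without the called genes. Identifiers without a gene symbol were not named. Raw sequencing reads were not analysed here.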

Results

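Cerebral organoids were grown from H9, an established line of human embryonic stem cells of wild-type genotype. From day 20 to day 60 their medium was renewed daily and held DMSO, the solvent control, 10 µM DEAB or 18.5 µM MTK. DEAB (diethylaminobenzaldehyde) is an inhibitor of aldehyde dehydrogenases, the enzymes that make retinoic acid from retinal. MTK is montelukast, an asthma drug that blocks the cysteinyl leukotriene receptor CYSLTR1. The title of the series concerns montelukast, autism-like behaviour and retinoic acid signalling in neurons. The comparisons asked what each compound changed against DMSO, and how the compounds differed, with DEAB as a reference for lower retinoic acid synthesis.

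At day 60 the organoids were dissociated and single-cell transcriptomes were counted in 9 libraries, 3 per treatment. The files held 91485 cell barcodes and 218078927 unique molecular identifiers (UMIs, each standing for 1 captured transcript), from 10045899 UMIs in MTK replicate 3 to 50659385 in DEAB replicate 3. After filtering, 81810 cells were kept, from 4306 in DMSO replicate 2 to 14492 in DEAB replicate 3. The median UMI count per kept cell was 1987 ± 394 in DMSO, 1907 ± 379 in DEAB and 1632 ± 323 in MTK (mean ± SD, n = 3 libraries). The median number of genes per cell was 953 ± 143, 942 ± 170 and 819 ± 112, and the median mitochondrial share was 10.0% ± 0.898, 9.01% ± 0.344 and 9.0% ± 0.634. None of these measures, nor the number of kept cells, differed between the 3 groups (exact permutation test, 2-sided, adjusted p = 0.504 for each). The labels number the libraries as biological replicates without saying what separates the cultures, so p-values measure the spread between these libraries. UMIs of the 4 lung genes SFTPC, SFTPB, SFTPA1 and SCGB3A2, chosen after their values were seen, stood at 3.69 CPM, the usual scaling of a count to its library total, in DEAB replicate 3. They stood at 2.75 CPM in MTK replicate 2 and 7.37 in MTK replicate 3 (95% exact binomial intervals 3.18 to 4.26, 2.13 to 3.49 and 5.78 to 9.25). The other 6 libraries, all DMSO libraries among them, held at most 0.412 CPM (0 to 5 UMIs) of these 4 genes and are called low in lung transcripts. They were not free of them. SCGB1A1, a lung gene outside the 4, had 1, 0 and 16 UMIs in DMSO replicates 1 to 3, 7, 11 and 70 in DEAB and 6, 12 and 47 in MTK. Any batch that the 4 genes mark held no control library. Of MTK, replicate 1 alone is among these 6, so fits to them assume that it varies like the other groups.

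The organoids held neurons, dividing cells and radial glia, the stem cells of the developing brain. Clustering gave 10 clusters, numbered from 0. Of the neuron-like clusters, cluster 0 was led by the interneuron genes SST, ERBB4, LHX6 and MAF, cluster 2 by COL1A2, RASD1 and GAD2, and cluster 8 by PDYN, TAC1, EBF1 and NEUROD6. Cluster 2 had 6 of 8 inhibitory neuron markers raised 1.5-fold, but only 1 of 11 markers of neurons in general (mean log2 fold change -0.591). NES of radial glia, PCNA of cycling cells and HES6 and INSM1 of intermediate progenitors were raised in it too. Cluster 6 was led by SIX3, TLE4 and MEIS2, and cluster 3 by GNRH1 and NEFL together with the glycolysis and hypoxia genes ALDOC, PDK1 and HK2. Of the progenitor-like clusters, 5 and 9 were cycling cells led by histone genes and by CCNB1 and CDC20, and cluster 7 was radial glia led by FAM107A, PTN, SLC1A3 and LIX1. Cluster 4 held the radial glia marker HES1 and was led by the stress and hypoxia genes ADM, SLC2A1, BHLHE40, GDF15 and DDIT3. Cluster 1 was led by MROH8, the mitochondrial tRNA gene MT-TL1, LINC00632, PIGN, VEGFA and SLC3A2 and stayed unnamed, since of the fixed cell type markers only GAD1, of inhibitory neurons, was raised 1.5-fold in it and a name needed 3. Its cells had a median of 1508 UMIs, 744 genes and 7.45% mitochondrial UMIs, against medians of 1623 to 3461 UMIs in the other clusters. Whether it is a cell type, a stressed state or cells of low quality is open.

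Neuron-like cells made up 63.5% ± 3.36 of the cells in DMSO, 56.5% ± 0.379 in DEAB and 56.4% ± 1.64 in MTK (n = 3), a difference between the groups past the threshold (exact permutation test, adjusted p = 0.0482). The call was lost at clustering resolutions of 0.5 and 2, in clusters made per library and over all barcodes (exact permutation test, adjusted p = 0.307, 0.0536, 0.959 and 0.0536), and at 0.5 the shares were 49.3%, 47.8% and 47.5%. Since several genes that define clusters also differed between the groups, the cells were clustered again without the 312 genes called in any comparison, of which 69 had been among the variable genes. The share of neuron-like cells was then 66.2% ± 2.93, 61.2% ± 0.227 and 60.7% ± 0.421 (exact permutation test, adjusted p = 0.0214). The unnamed cluster rose from 7.48% ± 1.76 in DMSO to 13.1% ± 3.98 in DEAB and 17.1% ± 2.07 in MTK (exact permutation test, adjusted p = 0.0429). Its call was lost without DMSO replicate 1, 2 or 3 (adjusted p = 0.0696, 0.0911 and 0.0857 by the same exact test) and without MTK replicate 1 or 2 (0.118 and 0.0964). In the clustering with all genes its share was 10.2% ± 1.23, 17.4% ± 4.00 and 20.6% ± 3.15 (exact permutation test, adjusted p = 0.0482). That call was lost at a resolution of 0.5 (19.9%, 21.9% and 25.6%) and in clusters made per library (17.7%, 18.6% and 22.1%), with exact adjusted p = 0.307 and 0.959, over all barcodes (0.0536) and without any 1 library but MTK replicate 3 (0.0536 to 0.0964). In the clustering without called genes, progenitor-like cells made up 26.3% ± 2.93, 25.7% ± 4.02 and 22.2% ± 1.67, which did not differ (exact permutation test, adjusted p = 0.268). With all genes they did not differ either (exact permutation test, adjusted p = 0.354). Between pairs of groups, 3 libraries against 3 cannot give an exact p under 0.1, and each compound against DMSO gave 0.1 for neuron-like cells. With cells of at least 1000 detected genes and at most 10% mitochondrial UMIs, in the clustering without called genes, the shares of neuron-like cells were 46.3%, 47.2% and 44.6%. They no longer differed (exact permutation test, adjusted p = 0.918). The unnamed cluster was then 6.02%, 8.82% and 9.60% (exact permutation test, adjusted p = 0.6; 0.525 in the clustering with all genes). This filter changes the limits on genes and on mitochondrial share together. The lower share of neuron-like cells in the clustering with all genes had also been lost without every library but MTK replicate 3 (exact adjusted p from 0.0536 to 0.0964). Within the neuron-like class, cluster 6 was 20.2% of all kept cells in DMSO, 10.8% in DEAB and 12.4% in MTK. Cluster 0 was 19.0%, 28.4% and 26.7%. Cluster 3, led in part by hypoxia and glycolysis genes, was 10.5% ± 0.970, 5.72% ± 0.614 and 6.06% ± 0.321, and cluster 8 was 7.18%, 4.64% and 4.76%. None of these shares passed the threshold (exact permutation test over the 3 groups, adjusted p = 0.0714 for cluster 3, whose p was 0.0214, and 0.107 for each of the others). In the clustering without called genes, the cluster closest to cluster 3, with 57.6% of its cells from it, was 13.1%, 10.4% and 10.1% (exact permutation test, p = 0.0214, adjusted p = 0.0952).

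**Figure D1:**
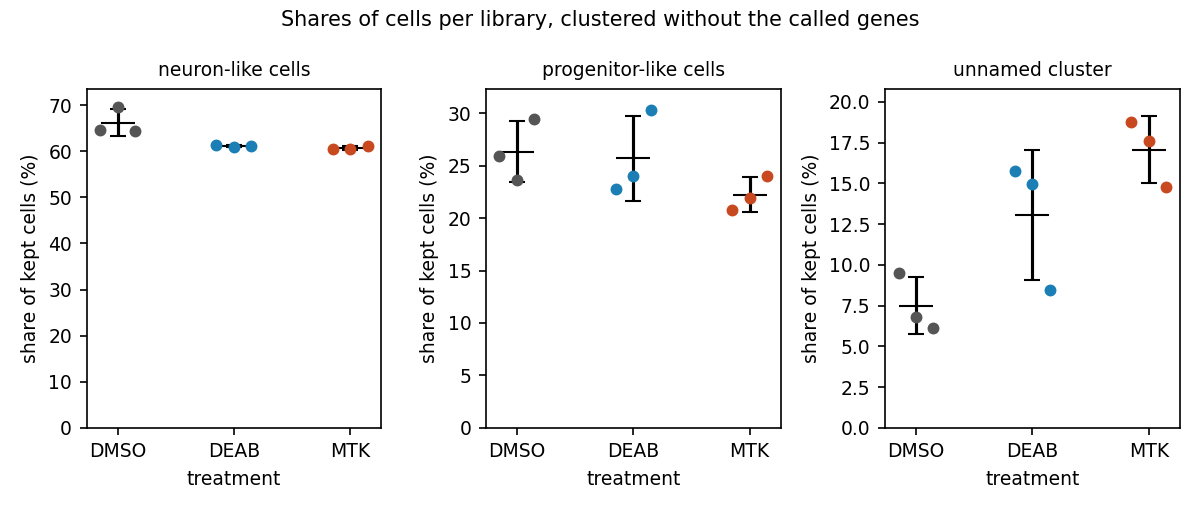
Share of kept cells (percent) in neuron-like cells, progenitor-like cells and the unnamed cluster for each treatment, after clustering without the called genes. Points are libraries, and bars are the mean ± SD of 3 libraries; the mean of the unnamed cluster was 7.48% in DMSO, 13.1% in DEAB and 17.1% in MTK.

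With montelukast, BHLHE40, SLC3A2, NQO1 and ADM were higher and ID4 and FOXP2 lower than in DMSO. All of these but BHLHE40 and SLC3A2 lost their calls in some fits without 1 library, as given below. BHLHE40, a transcriptional repressor induced by hypoxia that also acts in the circadian clock, rose from 30.3 ± 0.645 to 58.8 ± 2.77 CPM (mean ± SD, n = 3; log2 fold change 0.96 ± 0.08 SE, adjusted p = 0.000927). SLC3A2, the heavy chain of several amino acid transporters, rose from 85.4 ± 1.29 to 160 ± 6.40 CPM (log2 fold change 0.90 ± 0.08, adjusted p = 0.000927). NQO1, a quinone reductase induced by the oxidative stress regulator NRF2, rose from 11.2 ± 2.35 to 21.6 ± 3.16 CPM (0.94 ± 0.16, adjusted p = 0.0391). ADM, which encodes the hypoxia-induced peptide adrenomedullin, rose from 46.7 ± 2.73 to 80.7 ± 13.2 CPM (0.78 ± 0.13, adjusted p = 0.0293). ID4, an inhibitor of neural differentiation factors, fell from 74.1 ± 11.2 to 37.2 ± 2.34 CPM (-0.99 ± 0.13, adjusted p = 0.0133). The transcription factor FOXP2, needed for speech circuits, fell from 39.0 ± 5.86 to 19.7 ± 1.76 CPM (-0.98 ± 0.15, adjusted p = 0.0242).

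In all cells, 47 of 17420 tested genes differed between MTK and DMSO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 29 higher and 18 lower. Of all tested genes, 16.97% had no overlap between the libraries of the groups, where chance gives 10%. TNC, the matrix protein tenascin-C of outer radial glia, fell from 33.5 ± 3.21 to 18.2 ± 1.95 CPM (log2 fold change -0.89 ± 0.11, adjusted p = 0.0133). SLC1A3, the glutamate transporter of radial glia and astrocytes, fell from 44.0 ± 5.09 to 27.2 ± 1.66 CPM (-0.69 ± 0.10, adjusted p = 0.0202). LIX1, also a leading gene of the radial glia cluster, fell too (-0.75 ± 0.10, adjusted p = 0.0169). The transcription factors PBX3 (-0.94 ± 0.15), FOXP4 (-0.73 ± 0.13) and TSHZ1 (-0.66 ± 0.11), the neuronal membrane protein gene ISLR2 (-0.96 ± 0.13) and LINC00581 (-0.76 ± 0.12) fell as well. Among other genes that rose were the methyltransferase gene SMYD3 (0.92 ± 0.11), SUPT3H (0.85 ± 0.15), ANAPC1, a subunit of the anaphase-promoting complex (0.76 ± 0.12), and LINC00632 (0.74 ± 0.12). So did the ubiquitin-conjugating enzyme UBE2E2 (0.71 ± 0.11) and the cadherin-linked protein gene CTNNA2 (0.68 ± 0.12). On GRCh38, BHLHE40 lies on chromosome 3 from 4979116 to 4985323 and SLC3A2 on chromosome 11 from 62856102 to 62888875, both on the plus strand. BHLHE40, ID4, TNC, FOXP2, NQO1 and LINC00632, the last of which overlaps CDR1, have annotated genes on the opposite strand, and no source used here says whether counting used strand, so reads of such pairs cannot be told apart. SLC3A2 and LINC00632 also led the unnamed cluster, and BHLHE40 and ADM led cluster 4, whose shares were 10.2% ± 1.23 and 4.16% ± 0.364 in DMSO and 20.6% ± 3.15 and 6.03% ± 0.565 in MTK. The count was 12 without the cells of the unnamed cluster, 4 with the libraries high in lung transcripts as a batch term, 6 in the 6 libraries without them, 5 with the stricter filter on genes and mitochondrial share and 233 by DESeq2. It fell to 6, 10 and 25 without DMSO replicates 1, 2 and 3 and to 3 without MTK replicate 1 or 2. Of the 20 named genes, 4, 5 and 12 passed without DMSO replicates 1, 2 and 3, 2, 2 and 11 without MTK replicates 1, 2 and 3, and 17, 16 and 18 without DEAB replicates 1, 2 and 3. BHLHE40 and SLC3A2 passed in all 9 of these fits (adjusted p at most 0.013 for each). ADM lost its call without any 1 of the DMSO or MTK libraries. NQO1 lost it without DMSO replicate 2 or 3, DEAB replicate 1 or any 1 of the MTK libraries. FOXP2 lost it without DMSO replicate 1 or 2 or any 1 of the MTK libraries, and ID4 without DMSO replicate 1 or 2 or MTK replicate 1 or 2.

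**Figure D2:**
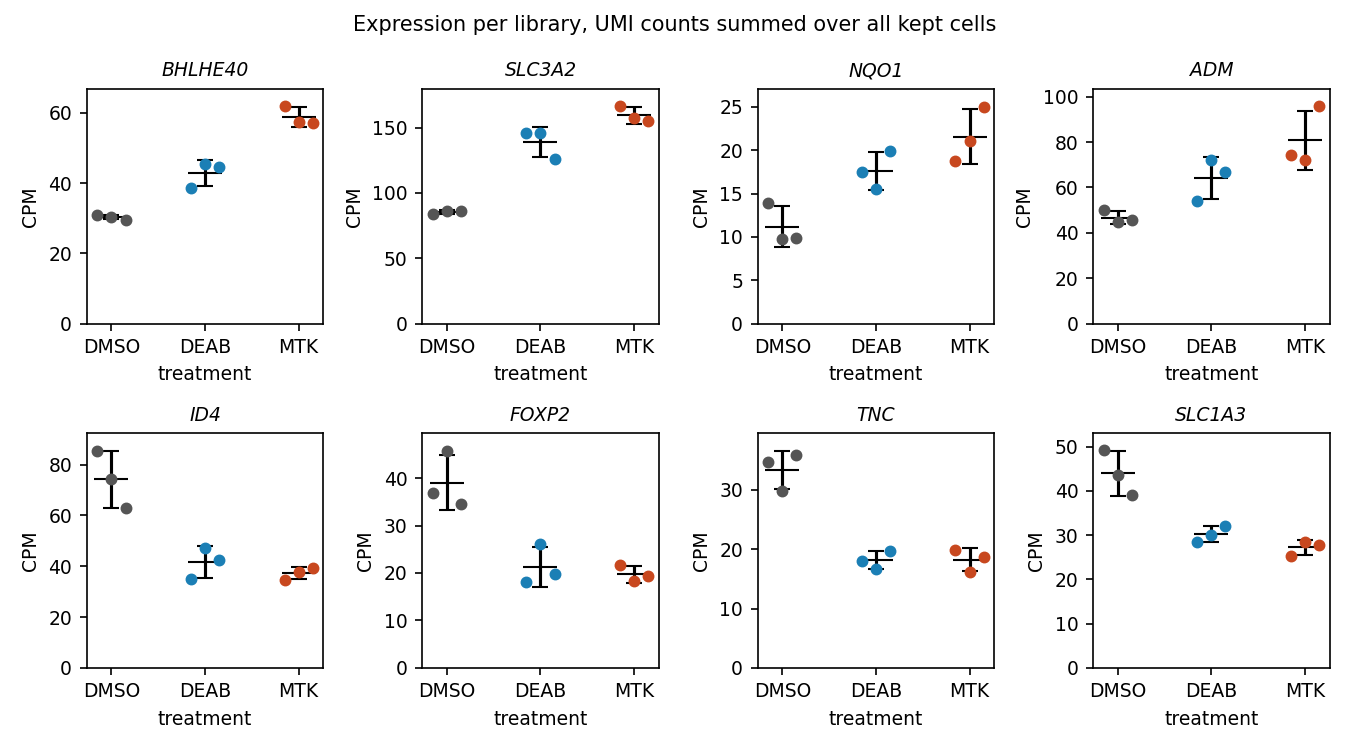
Expression of 8 named genes in CPM, from UMIs summed over all kept cells, for each treatment. Points are libraries, and bars are the mean ± SD of 3 libraries; BHLHE40 lay at 30.3 CPM in DMSO, 42.9 in DEAB and 58.8 in MTK, and TNC at 33.5, 18.1 and 18.2.

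Of the gene lists fixed in advance, 16 of 40 differed between MTK and DMSO in all cells (camera with a preset correlation, adjusted p under 0.05), and none did with the correlation estimated from the data. The 25 tested genes of radial glia identity fell together (adjusted p = 8.81e-11; adjusted p = 0.195 with an estimated correlation). All 25 had a negative log2 fold change, with a median of -0.31. Of these, 4 fell over all genes tested, namely TNC, SLC1A3, ID4 and FAM107A (-0.65 ± 0.10), and 14 when adjusted over the list alone. The 40 genes of the cell cycle all lay lower, with a median of -0.26 (adjusted p = 9.96e-09; adjusted p = 0.464 with an estimated correlation). None passed over all genes or adjusted over the list alone (0 of 40), and CENPF had -0.45 ± 0.13 and TOP2A -0.48 ± 0.14. The share of cluster 7 (radial glia) was 7.52% ± 0.325 in DMSO and 6.21% ± 0.390 in MTK. Those of the cycling clusters 5 and 9 were 10.3% ± 1.99 and 4.28% ± 0.309 in DMSO and 7.69% ± 1.97 and 3.04% ± 0.0208 in MTK. Of the signalling lists, WNT genes fell (18 genes, median -0.47, adjusted p = 5.89e-05; adjusted p = 0.134 with an estimated correlation). So did sonic hedgehog genes (11 genes, median -0.50, adjusted p = 0.00114, and adjusted p = 0.312 with an estimated correlation) and NOTCH genes (16 genes, median -0.29, adjusted p = 0.00114, and adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone, 4 WNT, 4 sonic hedgehog and 0 NOTCH genes were lower, and none of them over all genes. Examples were the WNT effector LEF1 (log2 fold change -1.18 ± 0.30, adjusted p = 0.146), the receptor FZD8 (-0.73 ± 0.16, 0.0932) and the hedgehog effector GLI3 (-0.73 ± 0.19, 0.155), given as values without a call.

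The lists of oxidative stress and NRF2 (15 genes, adjusted p = 1.58e-05) and of the unfolded protein response (22 genes, adjusted p = 0.0122) rose with MTK in all cells (adjusted p = 0.312 with an estimated correlation for each). Of the former, 3 members rose over all genes and 4 adjusted over the list alone. Among them were OSGIN1, an oxidative stress gene (log2 fold change 1.70 ± 0.27, adjusted p = 0.0257), NQO1 and FTL, the ferritin light chain (0.53 ± 0.07, adjusted p = 0.0161). SQSTM1, an autophagy receptor induced by NRF2, had 0.42 ± 0.09 (adjusted p = 0.067). Of the latter, PPP1R15A, a regulator of translation under stress, rose (0.49 ± 0.08, adjusted p = 0.0307), and adjusted over the list alone 9 members were higher and 3 lower. Hypoxia (22 genes, adjusted p = 0.0116) and glycolysis genes (17, adjusted p = 0.013) rose by camera, with adjusted p = 0.298 and 0.316 with an estimated correlation. These calls were lost without DMSO replicate 3 (0.0586 and 0.0903), and in the 6 libraries low in lung transcripts hypoxia, glycolysis and NRF2 were at 0.0737, 0.101 and 0.0854. Of the hypoxia genes 3 rose over all genes, ADM, the glucose transporter SLC2A3 (0.60 ± 0.09, adjusted p = 0.0194) and ANKRD37 (0.49 ± 0.09, adjusted p = 0.0407). Adjusted over the list alone 6 were higher and 1 lower, while 2 glycolysis genes were higher over that list alone and 0 over all genes. CDKN1A, a cell cycle inhibitor induced by p53, rose as well (0.62 ± 0.10, adjusted p = 0.0305). Genes of mesenchymal cells and extracellular matrix, another cell type an organoid can hold, were lower (18, median -0.40, adjusted p = 0.00575; adjusted p = 0.33 with an estimated correlation), but not in the 6 libraries low in lung transcripts (0.0622). Immediate early genes, which respond to dissociation, were lower too (21, median -0.24, adjusted p = 0.0336; adjusted p = 0.551 with an estimated correlation). That call was lost without DMSO replicate 3 (0.265), MTK replicate 2 (0.192) or MTK replicate 3 (0.0602), with doublets kept (0.0613), with the lung batch term (0.131) and in the 6 libraries (0.639). Of these, 1 mesenchymal gene and 0 immediate early genes were lower adjusted over the list alone, and 0 of either over all genes.

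Of the known targets of the compounds, the retinoic acid enzymes ALDH1A1, ALDH1A2 and ALDH1A3 and the receptor CYSLTR1 were at the limit of detection. Named after their counts were seen, they had 5, 22, 2 and 1 of 185569064 UMIs in kept cells. None could be tested at this depth. Retinoic acid synthesis and transport (14 tested genes, adjusted p = 0.511), retinoic acid receptors (12, adjusted p = 0.347), the leukotriene pathway (9, adjusted p = 0.511) and the aldehyde dehydrogenase family (13, adjusted p = 0.561) did not differ between MTK and DMSO. None of their members passed over all genes or adjusted over the list alone. No tested member of the synthesis, receptor and leukotriene lists had an adjusted p under 0.194 (RARB) with MTK or 0.207 (PTGR1, a leukotriene reductase) with DEAB. The synthesis list and the aldehyde dehydrogenase family each had a median of 0.02 and a mean of -0.10, with camera's direction down. Single values were -0.54 ± 0.23 for the retinol dehydrogenase RDH10, -0.26 ± 0.16 for the retinoic acid binding protein CRABP2 (adjusted p = 0.37 and 0.551). They were 0.56 ± 0.16 for the receptor RARB, 0.22 ± 0.11 for RARA and -0.82 ± 0.36 for CYSLTR2 (adjusted p = 0.194, 0.463 and 0.378). The list of 16 genes known to be induced by retinoic acid was lower with MTK by camera, with members on both sides (median -0.62, adjusted p = 0.0132; adjusted p = 0.33 with an estimated correlation), a call lost without MTK replicate 1 (0.0758). Of these, TSHZ1 alone passed over all genes, and adjusted over the list alone 3 were lower and 2 higher, with RARRES2 at -0.86 ± 0.17, MEIS2 at -0.58 ± 0.13 and RARB at 0.56 (adjusted p = 0.0654, 0.0789 and 0.194). MEIS2 leads cluster 6 (20.2% of cells in DMSO, 12.4% in MTK), and this shift may lower it. The 103 tested autism risk genes did not differ (median -0.05, adjusted p = 0.169, passing without MTK replicate 2 at 0.0446), with FOXP2 alone past the threshold over all genes and 4 genes lower when adjusted over the list alone. Presynaptic and postsynaptic genes (31 each) did not differ (adjusted p = 0.268 and 0.62), though the presynaptic list passed without DMSO replicate 3 (0.0107).

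Many of the genes that differed from DMSO with montelukast also differed with DEAB. Both comparisons use the same 3 DMSO libraries, so a deviation of those libraries would show in both. SLC3A2 rose from 85.4 ± 1.29 to 139 ± 11.5 CPM (n = 3; log2 fold change 0.70 ± 0.08, adjusted p = 0.00721). BHLHE40 rose to 42.9 ± 3.69 CPM (0.51 ± 0.08, adjusted p = 0.0414) and SMYD3 from 14.0 ± 1.35 to 27.7 ± 2.66 CPM (0.98 ± 0.11, adjusted p = 0.00721). TNC fell from 33.5 ± 3.21 to 18.1 ± 1.52 CPM (-0.89 ± 0.11, adjusted p = 0.0151). ID4 fell to 41.5 ± 6.25 CPM (-0.83 ± 0.13, adjusted p = 0.0362) and PBX3 from 177 ± 38.1 to 83.6 ± 9.70 CPM (-1.08 ± 0.15, adjusted p = 0.0215). The largest named fall was that of SLITRK6, a regulator of neurite growth (-1.10 ± 0.18, adjusted p = 0.0414). FOXP2 (-0.86 ± 0.14), FOXP4 (-0.75 ± 0.12), the guidance factor SEMA3C (-0.80 ± 0.14), ISLR2 (-0.78 ± 0.13), TSHZ1 (-0.64 ± 0.11) and ZNF503 (-0.58 ± 0.10) also fell. The other named rises were those of PLS3 (0.86 ± 0.13), PDZRN4 (0.67 ± 0.11), GTDC1 (0.64 ± 0.10), EXOC4 (0.56 ± 0.09), the syntaxin STX8 (0.52 ± 0.09), RABGAP1L (0.50 ± 0.08) and the kinase MAPK10 (0.49 ± 0.08). PLS3 and PDZRN4 also led cluster 0. In all, 36 genes differed between DEAB and DMSO (edgeR, adjusted p under 0.05), 22 higher and 14 lower, and 16.73% of the 17420 genes had no overlap, where chance gives 10%. The count was 193 by DESeq2, 0 with the stricter filter on genes and mitochondrial share, where MTK had 5, 8 without the cells of the unnamed cluster, 7 with the lung batch term and 3 in the 6 libraries low in lung transcripts. Without 1 library it was 2, 8 and 27 (DMSO replicates 1, 2 and 3), 4, 10 and 5 (DEAB) and 11, 9 and 44 (MTK). Of the 20 named genes, 1, 4 and 10 passed without those DMSO libraries, 2, 5 and 3 without those of DEAB and 4, 4 and 18 without those of MTK. SMYD3 passed in all 9 fits, and SLC3A2 in all but the fit without DMSO replicate 1 (adjusted p = 0.0552).

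With DEAB, 12 of 40 lists differed from DMSO in all cells by camera, and none with an estimated correlation. Radial glia identity fell (25 genes, median -0.37, adjusted p = 8.62e-09; adjusted p = 0.3 with an estimated correlation), with 3 members lower over all genes (TNC, ID4 and FAM107A, the last at -0.58 ± 0.10) and 12 adjusted over the list alone. Sonic hedgehog (median -0.42, adjusted p = 0.00133), WNT (median -0.28, adjusted p = 0.00236) and the transcripts of the mitochondrial genome (median -0.22, adjusted p = 0.000433) were lower too, at adjusted p = 0.455, 0.3 and 0.616 with an estimated correlation. Of these, 4, 4 and 3 members were lower adjusted over the list alone and 0 over all genes. The oxidative stress and NRF2 list rose (median 0.07, adjusted p = 0.00133; adjusted p = 0.524 with an estimated correlation), with 0 members over all genes and 7 adjusted over the list alone. NQO1 had 0.66 ± 0.16 (adjusted p = 0.152) and OSGIN1 1.14 ± 0.26 (0.122). The ribosomal protein list (55 genes, median -0.10, adjusted p = 0.00228) fell, but not without DMSO replicate 3 (0.583), and its adjusted p with an estimated correlation was 0.667. The list of forebrain identity genes (13, median -0.45, adjusted p = 0.0093) was lower by camera, with 4 lower and 1 higher adjusted over the list alone, a call lost without DMSO replicate 1 (0.0555) and with an estimated correlation (adjusted p = 0.455). Immediate early genes were lower (21, median -0.30, adjusted p = 0.00228; adjusted p = 0.616 with an estimated correlation; 0 over all genes or adjusted over the list alone), but not without DMSO replicate 3 (0.0914) or DEAB replicate 2 (0.0604). LEF1 had a log2 fold change of -1.38 ± 0.29 (adjusted p = 0.0887) and SIX3 -0.69 ± 0.19. This forebrain gene leads cluster 6 (20.2% of cells in DMSO, 10.8% in DEAB), and this shift may lower it. DEAB did not change retinoic acid synthesis and transport (median -0.13, adjusted p = 0.183), receptors (0.463) or retinoic acid induced genes (0.254; median -0.11 but mean 0.06). The synthesis list passed without DEAB replicate 2 (0.0408) or 3 (0.0482), and the induced genes without DEAB replicate 2 (0.0144). Of the induced genes TSHZ1 fell over all genes, and 2 were higher and 4 lower adjusted over the list alone, while 0 synthesis and receptor genes passed either way. RDH10 was at -0.58 ± 0.22, CRABP2 at -0.41 ± 0.15, RARA at 0.28 ± 0.11 and RARB at 0.35 ± 0.16 (adjusted p = 0.392, 0.358, 0.389 and 0.488). The leukotriene, aldehyde dehydrogenase, autism, presynaptic and postsynaptic lists did not differ either (adjusted p = 0.959, 0.786, 0.327, 0.18 and 0.97). Camera gave the leukotriene list the direction down while its median was 0.08, the postsynaptic list had a median of -0.02 and a mean of 0.01, and adjusted over the list alone 1 leukotriene gene was lower. Of the autism risk genes FOXP2 fell over all genes, and 1 was higher and 4 lower adjusted over the list alone. The presynaptic list passed without DMSO replicate 3 (0.00498).

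Montelukast and DEAB were set against each other directly, since a drug acting through retinoic acid synthesis would be read against the inhibitor of that synthesis. Between them, 0 of 17420 genes differed in all cells by edgeR, 505 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. With no filter on low counts the count was 106, and without DEAB replicate 1 it was 1. BHLHE40 was nominally higher with MTK (58.8 ± 2.77 against 42.9 ± 3.69 CPM, log2 fold change 0.45 ± 0.08). The kinetochore gene SKA3 (-0.49 ± 0.11), the endothelin receptor EDNRB (-0.69 ± 0.16), CDR1 (-1.24 ± 0.29) and TFPI (-1.64 ± 0.35) were nominally lower, all without a call. No overlap was seen for 8.37% of genes, where chance gives 10%. Of the lists, 11 of 40 differed by camera and none with an estimated correlation. Cell cycle genes were lower with MTK than with DEAB (median -0.24, adjusted p = 8.24e-11; adjusted p = 0.626 with an estimated correlation). Of the 40, 0 passed over all genes or adjusted over the list alone, with CCNB1 at -0.35 ± 0.11 as an example. Ribosomal protein genes were higher (all 55, median 0.09, adjusted p = 3.58e-06; 0.74 as the adjusted p with an estimated correlation), but not past the threshold without MTK replicate 2 (0.0859). The 5 tested hindbrain genes were lower (median -1.60, adjusted p = 0.00496; adjusted p = 0.26 with an estimated correlation), 2 of them adjusted over the list alone, but not in the 6 libraries low in lung transcripts (0.127). Retinoic acid synthesis, receptors and induced genes did not differ (adjusted p = 0.539, 0.75 and 0.269), the receptors having a median of -0.03 and a mean of 0.02, and 2 induced genes were lower adjusted over the list alone. The induced genes passed without DEAB replicate 1 (0.013) and with no filter on low counts (0.0417).

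Across the 17420 genes, the log2 fold changes against DMSO of MTK and of DEAB had a Pearson correlation of 0.665 and a covariance of 0.0782, and 74.95% of genes had the same sign. Genes are not independent replicates, and both comparisons use the same 3 DMSO libraries. In 50 simulations of unchanged groups against those controls the correlation was 0.476 on average (0.457 to 0.499), the covariance 0.038 (0.0358 to 0.0405) and the share of the same sign 66.1%. The simulated libraries were independent of each other. The simulated correlation, covariance and share of the same sign thus allow for the shared controls but not for a batch shared by treated libraries. The comparisons shared 14 higher and 11 lower genes, where independent lists would share 0.0366 and 0.0145, and 0 genes went in opposite directions. In 20 of the simulations of unchanged groups, 0 higher and 0.05 lower genes were shared on average. Without a simulated effect few genes are called in either comparison, so this number was near 0 by design. Neither it nor the values for independent lists tell how many genes unrelated responses would share against the same controls. BHLHE40, SLC3A2 and SMYD3 were among the shared rises, and TNC, ID4, PBX3, FOXP2, ISLR2, FOXP4 and TSHZ1 among the shared falls. With 3 DMSO libraries, the controls were too few to be divided between the comparisons. Without DMSO replicates 1, 2 and 3 the comparisons shared 2, 4 and 10 higher and 0, 4 and 7 lower genes. The numbers were 3, 7 and 4 higher and 0, 3 and 1 lower without those of DEAB, and 2, 2 and 18 higher and 0, 0 and 9 lower without those of MTK. In the 6 libraries low in lung transcripts the correlation was 0.467 and the covariance 0.0914, and no simulation was made for that design.

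**Figure D3:**
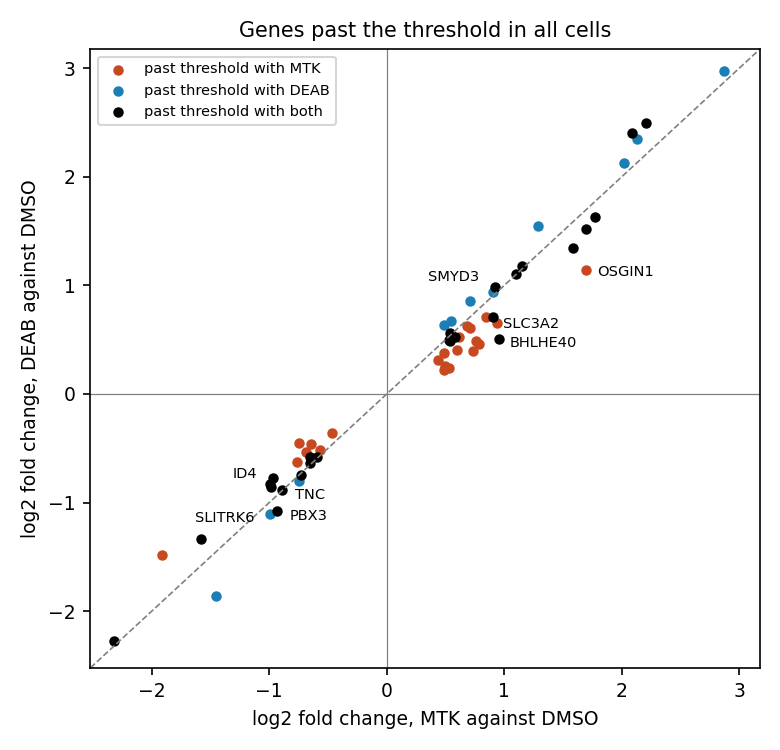
Log2 fold changes against DMSO of the genes past the threshold in all cells, for MTK (x axis) and DEAB (y axis), with equal change on the dashed line. Black points passed in both comparisons, red in MTK only and blue in DEAB only; the 14 higher and 11 lower shared genes lie in the upper right and lower left, and no gene passed in opposite directions.

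In progenitor-like cells (clusters 4, 5, 7 and 9), FTL, which encodes the light chain of the iron store ferritin, was higher with montelukast than in DMSO. It rose from 3214 ± 181 to 5723 ± 375 CPM (n = 3, log2 fold change 0.83 ± 0.08, adjusted p = 0.000441). BHLHE40 rose from 66.8 ± 7.50 to 146 ± 21.0 CPM (1.14 ± 0.12, adjusted p = 0.0016). SLC3A2 rose from 113 ± 8.71 to 198 ± 11.5 CPM (0.82 ± 0.10, adjusted p = 0.00289) and ADM from 105 ± 13.7 to 202 ± 17.4 CPM (0.94 ± 0.13, adjusted p = 0.0114). NR1D1, a repressor of the circadian clock (1.31 ± 0.19), NQO1 (1.01 ± 0.18), NOV (1.44 ± 0.20), IMMP2L (1.47 ± 0.23), CADM2 (1.10 ± 0.19) and MARCH1 (1.00 ± 0.15) rose as well (adjusted p from 0.0116 to 0.0335). TNC (-0.82 ± 0.12, adjusted p = 0.0134), ID4 (-0.84 ± 0.14, adjusted p = 0.0259), RARRES2, a gene named for its response to retinoids (-0.72 ± 0.14, adjusted p = 0.0473), ST6GALNAC5 (-0.76 ± 0.14) and B3GAT2 (-1.97 ± 0.36) fell. FTL has near-identical processed pseudogenes, from which its reads cannot be told apart here, so its level is uncertain. In all, 31 of 14224 genes differed (edgeR), 26 higher and 5 lower. Hypoxia genes (22, median 0.29, adjusted p = 1.05e-08), glycolysis genes (17, all positive, median 0.24, adjusted p = 7.57e-08) and the oxidative stress and NRF2 list (15, median 0.32, adjusted p = 3.33e-08) rose, at adjusted p = 0.229, 0.195 and 0.195 with an estimated correlation. Over all genes 3, 1 and 4 members were higher, and adjusted over the list alone 8, 7 and 9, with 1 hypoxia gene lower. ANKRD37 (0.78 ± 0.12), SLC2A3 (0.81 ± 0.12), the glycolytic enzyme GPI (0.59 ± 0.10), SQSTM1 (0.66 ± 0.11) and OSGIN1 (1.66 ± 0.29) were among them (adjusted p from 0.0134 to 0.0319). The unfolded protein response rose (22 genes, median 0.26, adjusted p = 5.74e-05; adjusted p = 0.275 with an estimated correlation; 9 members adjusted over the list alone), with PPP1R15A at 0.71 ± 0.12 (adjusted p = 0.0276). CDKN1A rose by 0.74 ± 0.12 (adjusted p = 0.0206).

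Cell cycle (40 genes, median -0.18, adjusted p = 1.05e-08), radial glia (25, median -0.27, adjusted p = 7.57e-08) and sonic hedgehog genes (10, median -0.48, adjusted p = 0.000588) fell with MTK in progenitor-like cells, at adjusted p = 0.229, 0.229 and 0.195 with an estimated correlation. Adjusted over the list alone, 2, 6 and 3 members were lower, and over all genes 0, 2 (TNC and ID4) and 0. The retinoic acid induced list (12 genes, median -0.23) passed at adjusted p = 0.0497 but not without MTK replicate 2 (0.0588), with the lung batch term (0.0703), in the 6 libraries low in lung transcripts (0.0629) or with an estimated correlation (adjusted p = 0.25). RARRES2 was its only member past the threshold over all genes or adjusted over the list alone. The share of cluster 4, the stress-marked radial glia, was 4.16% ± 0.364 of kept cells in DMSO, 5.22% ± 0.797 in DEAB and 6.03% ± 0.565 in MTK (exact permutation test over the 3 groups, p = 0.0214, adjusted p = 0.0714; p = 0.1, the smallest possible, for MTK against DMSO). In the clustering without called genes, the matching cluster was 3.69%, 4.21% and 4.72% (exact permutation test, p = 0.146, adjusted p = 0.214). Since cluster 4 is set apart by genes such as BHLHE40, ADM and SLC2A3, leaving out its cells removes those with high levels of them. Without its cells, 1 gene differed between MTK and DMSO by edgeR (765 had an unadjusted p under 0.05), and the adjusted p of hypoxia was 0.235, of glycolysis 0.0093 and of NRF2 0.00466, with medians of 0.12, 0.15 and 0.23. The count of 31 was 75 by DESeq2, 10 with the lung batch term and 5 in the 6 libraries low in lung transcripts. It was 11, 8 and 15 without DMSO replicates 1, 2 and 3, 20 without DEAB replicate 2, and 4 without MTK replicate 1 or 2. Of the 15 named genes, 8, 6 and 8 passed without DMSO replicates 1, 2 and 3, 4, 4 and 10 without MTK replicates 1, 2 and 3, and 13, 10 and 15 without those of DEAB. FTL, BHLHE40 and SLC3A2 passed in all 9 fits.

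With DEAB, 2 genes differed in progenitor-like cells (edgeR, with 42 by DESeq2), MARCH1 (log2 fold change 1.12 ± 0.14) and TNC (-0.93 ± 0.11, adjusted p = 0.00947 for each). The count was 0 without DMSO replicate 1 or 2 or DEAB replicate 2 or 3 (adjusted p from 0.053 to 0.0706 for MARCH1 and TNC), 29 without DMSO replicate 3, and 3 without DEAB replicate 1, MTK replicate 1 or MTK replicate 3. Ribosomal protein genes fell (all 55, median -0.18, adjusted p = 8.1e-14; adjusted p = 0.373 with an estimated correlation), 0 of them over all genes or adjusted over the list alone, with RPL26 (-0.36 ± 0.11) as an example. Radial glia genes fell (median -0.34, adjusted p = 1.66e-10; adjusted p = 0.347 with an estimated correlation; 12 adjusted over the list alone). The oxidative stress and NRF2 list rose (median 0.13, adjusted p = 0.000113; adjusted p = 0.347 with an estimated correlation; 6 adjusted over the list alone). Hypoxia and glycolysis rose by camera (adjusted p = 0.00169 and 0.00309; 0.43 and 0.373 as adjusted p with an estimated correlation; 5 higher and 1 lower, and 0, adjusted over the list alone), but not without DMSO replicate 3 (0.0868 for each). The retinoic acid induced list fell (median -0.18, adjusted p = 0.0316; 2 lower adjusted over the list alone), but not without DEAB replicate 1 (0.0936) or with an estimated correlation (adjusted p = 0.347). Between MTK and DEAB, 0 genes differed by edgeR and 2 by DESeq2, with 561 at an unadjusted p under 0.05 and 61 with no filter. FTL was at 5723 ± 375 against 4088 ± 139 CPM (log2 fold change 0.49 ± 0.08, adjusted p = 0.259) and BHLHE40 at 0.63 ± 0.12 (adjusted p = 0.866). Hypoxia (median 0.18, adjusted p = 2.24e-05), glycolysis (0.16, adjusted p = 0.000482) and the unfolded protein response (0.18, adjusted p = 3.96e-05) were higher and the cell cycle (-0.14, adjusted p = 9.58e-06) lower with MTK than with DEAB, at adjusted p = 0.566 with an estimated correlation for each. Adjusted over the list alone, 2, 0, 3 and 0 members passed.

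In neuron-like cells few genes passed. With MTK, the ubiquitin-conjugating enzyme UBE2E2 (log2 fold change 0.73 ± 0.11, adjusted p = 0.0391) and STX8 (0.62 ± 0.09, adjusted p = 0.0373) rose. ID4 fell from 83.8 ± 12.4 to 42.4 ± 1.89 CPM (-0.98 ± 0.14, adjusted p = 0.0373) and PBX3 from 228 ± 50.4 to 114 ± 11.7 CPM, where it fell by 1.00 ± 0.15 on the log2 scale (adjusted p = 0.0496). With DEAB, ARHGAP18 (1.25 ± 0.19), SMYD3 (0.97 ± 0.14), GTDC1 (0.75 ± 0.11) and STX8 (0.55 ± 0.09) rose, and PBX3 (-1.12 ± 0.15), ID4 (-0.85 ± 0.14) and FOXP4 (-0.74 ± 0.12) fell (adjusted p from 0.0244 to 0.0482). These were among 7 and 12 genes of 15308 (edgeR, with 85 and 110 by DESeq2). Cluster 0 was 19.0% of all kept cells in DMSO, 28.4% in DEAB and 26.7% in MTK, and cluster 6 was 20.2%, 10.8% and 12.4%. CRABP2, which carries retinoic acid to its receptors, had -0.92 ± 0.18 with MTK without a call (adjusted p = 0.0883), RARB had 0.60 ± 0.16 (0.23), and TCF4, an autism risk gene, 0.52 ± 0.11 (0.126). The lists of retinoic acid synthesis and transport, receptors and induced genes did not differ with MTK in these cells (adjusted p = 0.267, 0.176 and 0.0991). Adjusted over the list alone, 5 induced genes were lower and 2 higher, 1 receptor gene higher and 1 synthesis gene lower. The induced genes passed without DMSO replicate 1 (0.0326) or DEAB replicate 1 (0.0474). By camera, WNT genes were lower with MTK (13 genes, median -0.43, adjusted p = 0.00815; adjusted p = 0.667 with an estimated correlation; 1 adjusted over the list alone). The axon growth and guidance list was lower (32, median -0.15, adjusted p = 0.00666; adjusted p = 0.667 with an estimated correlation), but not without MTK replicate 3 (0.066). Adjusted over the list alone 8 were lower and 1 higher, with SEMA3C at -0.92 ± 0.18 and CNTN2 at -0.96 ± 0.22. Hypoxia genes, higher in progenitor-like cells, were lower in neuron-like cells with MTK (22, median -0.10, adjusted p = 0.0355) and DEAB (median -0.13, adjusted p = 0.0225), at adjusted p = 0.667 and 0.628 with an estimated correlation. Of these, 2 and 0 were lower adjusted over the list alone and 0 over all genes. Cluster 3, led in part by hypoxia genes, was 10.5% of cells in DMSO, 5.72% in DEAB and 6.06% in MTK. The hypoxia call was lost with MTK without DMSO replicate 1 or 3 (0.126 and 0.0719) or MTK replicate 1 or 2 (0.456 and 0.0817). With DEAB it was lost without DMSO replicate 1 or 3 (0.0776 and 0.0517) or DEAB replicate 1 (0.0915). The autism risk list was lower by camera (103, median -0.07, adjusted p = 0.0296; adjusted p = 0.667 with an estimated correlation). Over all genes 0 passed, and 4 were lower and 1 higher adjusted over the list alone. The call was lost without DMSO replicate 1 (0.126) or MTK replicate 3 (0.371), or in the 6 libraries low in lung transcripts (0.256). With DEAB, WNT genes were lower (median -0.35, adjusted p = 0.0225; adjusted p = 0.628 with an estimated correlation; 1 adjusted over the list alone), but not without DMSO replicate 1 (0.0776). The count with MTK was 0, 1 and 3 without DMSO replicates 1, 2 and 3. It was 4 without DEAB replicate 1 or 3 or MTK replicate 3, and 0 and 1 without MTK replicates 1 and 2. With DEAB it was 0, 1 and 19 without the DMSO replicates, 0, 8 and 0 without those of DEAB and 0, 4 and 45 without those of MTK. Of the 4 named genes with MTK, 0, 0 and 2 passed without DMSO replicates 1, 2 and 3, 2, 1 and 2 without those of DEAB and 0, 0 and 1 without those of MTK. Of the 7 with DEAB it was, in the same order, 0, 0 and 4, 0, 3 and 0, and 0, 1 and 7. With the lung batch term the counts were 0 and 2, and in the 6 libraries low in lung transcripts 2 and 0. Between MTK and DEAB, 0 genes differed by edgeR and by DESeq2, with 343 at an unadjusted p under 0.05, 72 with no filter, and 1 without DEAB replicate 1.

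In the unnamed cluster, whose cell type is open, the metal-binding metallothioneins MT1X, MT1F and MT2A fell with both compounds. Its share was 10.2% in DMSO, 17.4% in DEAB and 20.6% in MTK. Called genes helped define it, so changes may reflect which cells enter it. MT1X fell from 125 ± 63.9 CPM in DMSO to 8.12 ± 2.55 in MTK (n = 3; log2 fold change -3.87 ± 0.47, adjusted p = 0.000504) and 16.4 ± 11.8 in DEAB (-2.77 ± 0.39, adjusted p = 0.00125). MT1F (-3.38 ± 0.40 and -3.03 ± 0.36) and MT2A (-2.89 ± 0.44 and -2.23 ± 0.39) followed. Reads of this close gene family cannot be told apart with certainty. BCAS3 (3.00 ± 0.46 with MTK, 3.19 ± 0.44 with DEAB), MARCH1 (2.52 ± 0.32, 2.67 ± 0.30), FGF12 (2.26 ± 0.36, 1.98 ± 0.35) and SMYD3 (2.00 ± 0.27, 2.15 ± 0.26) rose with both compounds. NSMCE2 rose with MTK (1.67 ± 0.25), and the heat shock gene HSPA6 with DEAB (3.09 ± 0.71). SLITRK6 fell with DEAB (-2.15 ± 0.39) and the phosphatase gene DUSP23 with MTK (-2.64 ± 0.50). Of 10607 genes, 191 differed between MTK and DMSO (76 higher, 115 lower) and 184 between DEAB and DMSO (69 and 115) by edgeR. Cholesterol synthesis genes fell with MTK (24 genes, median -0.31, adjusted p = 0.000432; adjusted p = 0.286 with an estimated correlation) and with DEAB (median -0.33, adjusted p = 1.32e-06; adjusted p = 0.1 with an estimated correlation). Of these, 1 and 3 passed over all genes and 6 and 10 adjusted over the list alone. INSIG1, a sterol sensor, fell by 0.49 and 0.52 on the log2 scale (adjusted p = 0.0463 and 0.0313), and SQLE (-0.57 ± 0.12) and STARD4 (-0.68 ± 0.14) with DEAB. Transcripts of the mitochondrial genome fell as well (13, median -0.30 and -0.34, adjusted p = 0.00054 and 0.00015; 0.696 and 0.814 as the adjusted p with an estimated correlation; 6 and 8 adjusted over the list alone). Among them was MT-ND1 (-0.72 ± 0.10 and -0.78 ± 0.10). The counts were 50 and 125 with the lung batch term and 22 and 88 in the 6 libraries low in lung transcripts. With MTK the count was 53, 72 and 213 without DMSO replicates 1, 2 and 3, 125 without DEAB replicate 2, and 35 without MTK replicate 1 or 2. With DEAB it was 58, 56 and 268 without the DMSO replicates, 66, 63 and 82 without those of DEAB and 123 without MTK replicate 1. The calls of DUSP23 (without MTK replicate 1 or 2, 0.0806 and 0.0539), HSPA6 (without DMSO replicate 1 or 2 or DEAB replicate 1, 0.151 at most) and SLITRK6 (without DMSO replicate 1, 0.0596) were lost. Between MTK and DEAB, 0 genes differed by edgeR or DESeq2, with 251 at an unadjusted p under 0.05 and 26 with no filter.

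The response to montelukast differed between neuron-like and progenitor-like cells for 125 of 15240 genes (edgeR interaction test, adjusted p under 0.05), 38 with a larger and 87 with a smaller log2 fold change in neuron-like cells. Without the cells of cluster 4, a setting added after the data were seen, 1 gene differed, TCF4 (917 had an unadjusted p under 0.05). BHLHE40, SLC2A1 and SLC2A3 are among the leading genes of cluster 4, which was 4.16% of kept cells in DMSO and 6.03% in MTK, so this setting removes cells chosen in part by the genes tested. FTL differed most clearly, with 0.18 in neuron-like and 0.83 in progenitor-like cells (difference -0.66 ± 0.06, adjusted p = 4.92e-07). Larger values in progenitor-like cells were found for DDIT4, an inhibitor of the growth regulator mTORC1 (difference -0.66 ± 0.07, adjusted p = 9.94e-06), GPI (-0.53 ± 0.08, 0.000934) and the glucose transporters SLC2A1 (-0.81 ± 0.14, 0.00272) and SLC2A3 (-0.70 ± 0.13, 0.00519). The same held for the chaperone HSPA5 (-0.64 ± 0.10, 0.000934) and BHLHE40 (0.25 against 1.14, difference -0.95 ± 0.20, adjusted p = 0.0161). CRABP2 had -0.92 in neuron-like and 0.36 in progenitor-like cells (difference -1.30 ± 0.22, adjusted p = 0.00272), neither past the threshold within its class. TCF4 went the other way, with 0.52 and -0.20 (difference 0.70 ± 0.09, adjusted p = 0.000232). With DEAB 13 genes differed, among them DDIT4 (-0.49 ± 0.07), TCF4 (0.61 ± 0.09) and JUN (-0.44 ± 0.08), and between MTK and DEAB 1 gene, FTL (0.09 against 0.49, difference -0.40 ± 0.06, adjusted p = 0.00681). Without cluster 4 the differences with MTK were -0.07 for FTL, -0.21 for DDIT4, -0.12 for GPI, -0.03 for SLC2A1, -0.08 for SLC2A3, -0.09 for HSPA5, -0.33 for BHLHE40 and -0.86 for CRABP2 (adjusted p from 0.694 to 0.994), and 0.61 for TCF4 (0.0102). With DEAB 14 genes differed without cluster 4, TCF4 and JUN among them (0.00521 and 0.029) but not DDIT4 (0.265), and between MTK and DEAB 0 (574 at an unadjusted p under 0.05; adjusted p of FTL 1.0). With all progenitor-like cells, FTL, DDIT4, GPI, SLC2A1, HSPA5 and TCF4 stayed past the threshold with MTK whichever library was left out. BHLHE40 did not without DMSO replicate 3, MTK replicate 1 or MTK replicate 2 (adjusted p = 0.111, 0.154 and 0.17), SLC2A3 not without MTK replicate 1 or 2 (0.0685 and 0.0791), and CRABP2 not without MTK replicate 2 (0.083). In the 6 libraries low in lung transcripts CRABP2 and SLC2A3 did not pass (adjusted p = 0.217 and 0.0687), nor did JUN with DEAB (0.16) or FTL between MTK and DEAB (0.0965). JUN was lost without DEAB replicate 1 or 3 (0.0791 and 0.112), and FTL between MTK and DEAB without DEAB replicate 1 or 3 or MTK replicate 1 or 2 (0.0523, 0.164, 0.222 and 0.117). The count of 125 fell to 75 without DMSO replicate 1, 36 and 40 without MTK replicates 1 and 2 and 28 in the 6 libraries low in lung transcripts. Within the neuron-like class cluster 0 was 19.0% of kept cells in DMSO and 26.7% in MTK and cluster 6 20.2% and 12.4%, while cluster 3, led in part by hypoxia and glycolysis genes, was 10.5% and 6.06%. The count of 13 was 6 and 123 without DMSO replicates 1 and 3, 8 without DEAB replicate 1 or 3 and 27 and 22 without MTK replicates 1 and 3. The single gene became 2 without DMSO replicate 3, 0 without DEAB replicate 3 or MTK replicate 1 and 5 without MTK replicate 3.

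**Figure D4:**
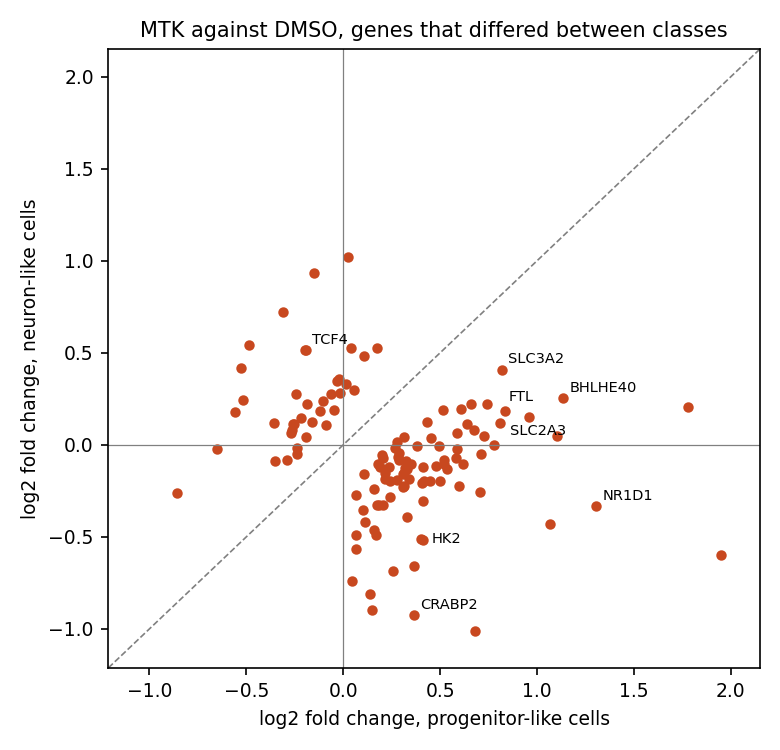
Log2 fold change of MTK against DMSO in progenitor-like cells (x axis) and neuron-like cells (y axis) for 124 of the 125 genes whose response differed between the classes, those with a value in both, with equal change on the dashed line. Of these, 86 lie below the line, among them FTL, BHLHE40, SLC2A3 and CRABP2, and 38 above it, among them TCF4.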

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

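The tests weighing the 3 patterns below and the interaction without cluster 4 were chosen after the results were seen. The ± of each share of change left, and of the immediate early genes, is an SE from resampling genes. Genes of the same libraries are not independent, so this SE does not measure the spread between libraries. The response to treatment differed between neuron-like and progenitor-like cells by the interaction test for 125 genes with MTK against DMSO, 13 with DEAB against DMSO and 1 between MTK and DEAB, with adjusted p under 0.05 for the difference itself. Without the cells of cluster 4 the counts were 1, 14 and 0, but its cells are set apart by some of the genes that differ, which lowers their difference by construction, so these counts do not tell where the difference lies. Shifts between the other clusters were not tested. Of the 10 splits of the 6 libraries into 3 and 3, the true one included, 1, 2 and 2 gave as many interaction genes, the highest other counts being 6, 57 and 20, and 10 splits are too few for a share under 0.05. The splits of DMSO replicates 1 and 2 with DEAB replicate 1, and of DEAB replicate 1 with MTK replicates 1 and 2, against the others gave the 57 and 20, several times the real counts, which points to a structure among the libraries other than the treatment.

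The genes higher with both compounds in all cells were tested against 3 technical explanations. Gene length was examined since the called genes are long (median 273 kb with MTK and 605 kb with DEAB, against 25.4 kb over all genes). Genes in the same broad bands of length and expression had a median log2 fold change of 0.02 with MTK and 0.06 with DEAB. These were at most 0.0608 of the median of the called genes, so the matched genes as a set shifted little. The called genes were chosen for large changes, so a low share follows largely from that choice. The bands may also not match the longest called genes. Whether length adds to their rise stays open. Without the cells of the unnamed cluster 0.834 ± 0.0811 of the change with MTK was left, so most of it stayed without this cluster. Without the libraries high in lung transcripts 1.01 ± 0.0403 of the change with DEAB was left (1.03 and 0.987 in DEAB replicates 1 and 2). Genes called over all DEAB libraries had to be high in each of them. A high share thus follows largely from how they were chosen and does not decide on that batch. The 0.97 ± 0.102 left with MTK rests on replicate 1 alone and leaves it open there too. A response of the cells to both compounds remains possible, but the 3 DMSO libraries are shared and none of them is high in lung transcripts. A batch of treated libraries as a whole thus cannot be excluded.

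The genes lower with both compounds in all cells, among them TNC, ID4 and FOXP2, were tested against a change in the shares of the clusters. With the same cluster shares in every library, 0.812 ± 0.0906 of their median change was left with MTK and 0.616 ± 0.105 with DEAB, so shares could account for a part with DEAB and the test does not settle it. Without the libraries high in lung transcripts 0.996 ± 0.0444 was left with DEAB (1.16 and 0.974 in replicates 1 and 2). Genes called over all DEAB libraries had to be low in each of them, so this share does not decide on that batch. With MTK 1.04 ± 0.0686 was left, where replicate 1 alone decides nothing. Lower expression within the clusters is the biological alternative, and single genes were not tested at equal shares.

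Hypoxia, glycolysis and oxidative stress genes were higher with MTK in progenitor-like cells, and cluster 4, the radial glia marked by such genes, had a mean share of 6.03% against 4.16% in DMSO (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give, and 0.0214 over the 3 groups, but 0.146 over the 3 groups when clustered without called genes). Without its cells 0.572 ± 0.0943 of the median change was left (hypoxia 0.29 to 0.12, glycolysis 0.24 to 0.15 and NRF2 0.32 to 0.23), but these cells are chosen by such genes, so whether a larger share of them accounts for a part stays open. Stress of dissociation would likely raise immediate early genes, whose median log2 fold change was -0.0405 ± 0.106, too wide to decide. Without the libraries high in lung transcripts 1.28 ± 0.129 of the change was left, but in MTK replicate 1 alone, so that batch stays open.

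For genes in all cells, 1, 1 and 10 of the 10 splits of the libraries gave counts as large as MTK against DMSO, DEAB against DMSO and MTK against DEAB (highest other counts 0, 2 and 37), in neuron-like cells 1, 1 and 10 (0, 0 and 33), in progenitor-like cells 1, 1 and 10 (1, 0 and 44) and in the unnamed cluster 1, 1 and 10 (1, 0 and 37). For lists, the splits as large were 1, 2 and 1 in all cells (highest other counts 13, 14 and 8), 5, 8 and 7 in neuron-like cells (13, 12 and 9), 1, 2 and 2 in progenitor-like cells (8, 14 and 10) and 4, 4 and 3 in the unnamed cluster (11, 7 and 6). Between MTK and DEAB, the split of DEAB replicates 1 and 2 with MTK replicate 1 against the 3 libraries high in lung transcripts called 37 genes in all cells, which points to a structure among the libraries other than the treatment. In each case 10 splits are too few for a share under 0.05.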

How the results depend on the processing

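The lung batch term, the 6 libraries low in lung transcripts, the fit without the unnamed cluster, the fit without cluster 4 and the clustering without called genes were chosen after the results were seen. In each triple below the order is MTK against DMSO, DEAB against DMSO and MTK against DEAB, and the cause of a difference was not tested unless the setting itself uses fewer cells or libraries. Leaving out 1 library gave 3 to 48, 2 to 44 and 0 to 1 genes in all cells (47, 36 and 0 in the fit reported), 0 to 7, 0 to 45 and 0 to 1 in neuron-like cells (7, 12, 0), 4 to 34, 0 to 29 and 0 in progenitor-like cells (31, 2, 0) and 35 to 213, 56 to 268 and 0 in the unnamed cluster (191, 184, 0). DESeq2 called 233 and 193 genes in all cells, 85 and 110 in neuron-like cells and 75, 42 and 2 in progenitor-like cells; with no filter on low counts 573, 489 and 106, then 316, 376 and 72, then 230, 200 and 61, and 372, 327 and 26 in the unnamed cluster. Fits of only the 2 groups gave 23 and 4 in all cells, 0 and 0 in neuron-like cells and 4 with DEAB in progenitor-like cells. Voom gave 74 and 15, all barcodes 79 and 57, the stricter filter 5 and 0, no unnamed cluster 12 and 8, equal depth 14 and equal cells 7 with DEAB. With doublets kept DEAB had 56 genes in all cells, 20 in neuron-like and 5 in progenitor-like cells. The batch term gave 4 and 7 in all cells, 0 and 2 in neuron-like cells, 10 with MTK in progenitor-like cells and 50 with MTK in the unnamed cluster. The 6 libraries gave 6 and 3, then 2 and 0, then 5, 1 and 1, then 22 and 88, and progenitor-like cells without cluster 4 gave 1. A resolution of 0.5 gave 11 and 7 in neuron-like cells, 5 with DEAB in progenitor-like cells and 389 with MTK in the unnamed cluster, a resolution of 2 gave 85 and 104 there, and clustering per library 16 in neuron-like cells and 32 in the unnamed cluster with MTK.

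With the replicate block, 19 and 6 genes were called in all cells, 0 and 7 in neuron-like cells, 118 with MTK in the unnamed cluster and 4 lists with MTK in neuron-like cells. The numbers do not pair the libraries: deviations of same-numbered libraries correlated between -0.15 and 0.171, and DEAB replicate 3 correlated best with MTK replicate 2 (0.367). Under the block the adjusted p by exact permutation was 0.139 for the neuron-like share and 0.0833 for the unnamed cluster. Clustered without called genes it was 0.0417 for each.

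With an estimated correlation 0 lists were called in every scope. Without 1 library the list counts were 13 to 17, 9 to 15 and 2 to 11 in all cells (16, 12, 11), 4 to 11, 2 to 10 and 0 to 4 in neuron-like cells (8, 5, 3), 11 to 17, 12 to 14 and 7 to 13 in progenitor-like cells (17, 14, 9) and 3 to 6, 3 to 6 and 0 to 4 in the unnamed cluster (4, 4, 3). The 6 libraries gave 9 and 4 (MTK against DMSO and against DEAB) in all cells, 10 with MTK in progenitor-like cells and 0 between MTK and DEAB in the unnamed cluster, and the batch term 8 with DEAB in neuron-like cells. Interaction counts were 36 to 159, 6 to 123 and 0 to 5 without 1 library, 195, 97 and 21 with no filter and 28 with MTK in the 6 libraries, and 1 and 0 (MTK against DMSO and against DEAB) without cluster 4.

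The neuron-like share had adjusted p (exact permutation) of 0.0214 to 0.0964 without 1 library, 0.307 and 0.0536 at resolutions of 0.5 and 2, 0.959 clustered per library, 0.0536 over all barcodes and 0.896 with the stricter filter; clustered without called genes 0.0107 to 0.0429 and 0.918. The unnamed cluster had 0.0214 to 0.118 and 0.6. The correlation of the MTK and DEAB responses was 0.576 to 0.745 without 1 library, 0.574 with no filter and 0.467 in the 6 libraries, and the covariance 0.0737 to 0.108, 0.0988 and 0.0475 with prior counts of 0.5 and 10, and 0.0914. Quality measures and the progenitor-like share stayed on their side of the threshold throughout. Of the values of named genes under alternatives, 2422 stayed on their side of the threshold, 921 lost a call and 45 gained one. For named lists the numbers were 989, 94 and 10, and no call had a reversed direction. Values that stayed include those without a call in the fit reported, so they are not a count of calls kept. All alternatives fixed in advance were run. Depth limits tests of ALDH1A1, ALDH1A2, ALDH1A3 and CYSLTR1, which had at most 22 UMIs each.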

Other observations

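The genes under the filter and the fits cluster by cluster were chosen after the results were seen. CYP26A1, induced by retinoic acid and breaking it down, was under the filter, with 19 UMIs in DMSO, 23 in DEAB and 1 in MTK. HOXA5, a hindbrain gene induced by retinoic acid, had 17, 30 and 0 UMIs, and STRA6, a vitamin A receptor, 38, 29 and 10. Not all untested genes were so low in MTK, with HOXA2 at 1, 9 and 5 and RBP7 at 17, 25 and 15. Depth was unequal, cells were few, HOXA5 came from 4 libraries, and no test was made.

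In progenitor-like cells the transcripts of the mitochondrial genome fell with MTK (13 genes, median -0.21, adjusted p = 5.74e-05; adjusted p = 0.275 with an estimated correlation; 1 adjusted over the list alone) and with DEAB (median -0.26, adjusted p = 6.19e-06; adjusted p = 0.347 with an estimated correlation; 9 adjusted over the list alone). NOTCH signalling genes, which keep radial glia undifferentiated, fell with MTK (14 genes, median -0.24, adjusted p = 0.00273; adjusted p = 0.195 with an estimated correlation; 0 adjusted over the list alone). Tested cluster by cluster by the same edgeR fit, the stress-marked radial glia of cluster 4 had 35 genes changed with MTK (17 higher and 18 lower) and 21 with DEAB, against 1 and 1 in the radial glia of cluster 7.

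The immunoglobulin gene IGKC, like the lung genes foreign to brain organoids, had 1530 UMIs in DEAB replicate 3, 659 in MTK replicate 2 and 13 in MTK replicate 3, against 47, 5 and 4 in DMSO replicates 1 to 3, 30 and 1 in DEAB replicates 1 and 2 and 0 in MTK replicate 1. The smallest difference between any 2 libraries was a chi-square per degree of freedom of 3.88, between DEAB replicate 1 and MTK replicate 1, where copies of a library would give about 1.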
